A study of Mus musculus with 48 samples.

How the data were processed

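Cerebral cortex RNA of 48 C57BL/6 mice aged 4 months was sequenced by the authors from Illumina TruSeq stranded libraries. Per the labels, reads were aligned with STAR 2.7.5c, handled with SAMtools 1.10 and counted with HTSeq 0.12.3 on GRCm38 (mm10). The deposited values are whole-number read counts per gene, and FPKM deposited beside them. The FPKM of each gene is its count times a factor set by the library and the gene, with a largest relative deviation of 4e-07. The annotation release and the strand setting of the counting are not given in the sources used here. Positions, transcript GC content and length came from the GENCODE annotation of GRCm38, which covered 99.1% of the gene identifiers. Symbols shared by 2 or more identifiers numbered 126, and genes were handled by identifier.

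Groups were taken from the labels, giving 6 genotypes with 24 females and 24 males. Of 48795 genes, 20843 (42.7%) were kept by filterByExpr with a minimum count of 10, and they held 99.95% of the reads. Counts were scaled by TMM and fitted with edgeR 4.0.16 in R 4.3.3 by quasi-likelihood (glmQLFit and glmQLFTest, two-sided), with all 48 libraries in 1 model of genotype and sex. The p-values were adjusted by the Benjamini-Hochberg method over all tested genes with a threshold of 0.05. They measure the spread between the mice as the labels name them. There were 12 contrasts: 7 between pairs of groups, 2 interactions and 3 averaged over the other gene's genotypes. Sex differences of 3 contrasts were tested with 12 genotype-by-sex groups. Log2 CPM used a prior count of 2. Mlh1 and Htt levels were compared between all 15 pairs of genotypes by exact permutation of the libraries, adjusted over the 15 pairs. Fold changes are given with their SE.

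A set of 49 gene lists was written before the data were examined and tested with camera in limma 3.58.1, with a preset inter-gene correlation of 0.01 and again with the correlation estimated. Adjustment was over the 49 lists. Directions of effects were compared over the 200 genes with the smallest p in Q140 against WT, beside 100 simulations with no effect. The positions were read with rtracklayer 1.62.0 and the labels with jsonlite 2.0.0.

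Genes named in the text followed a rule set before the data were examined. Mlh1 and Htt were always named. For Q140 against WT, Mlh1ko against WT, Q140_Mlh1ko against Q140 and the averaged knock-in effect, up to 8 genes that rose and 8 that fell with a mean log2 CPM of at least 0 were named, and for the other comparisons up to 3 each way. Where no gene passed, the 3 with the smallest p were named as not passing. From each list, up to 3 members with the smallest p were named where a member or the list passed. Outside this rule, some further members past the threshold over the list alone were named after their values were seen. Genes within 10 Mb of Mlh1 (277 kept) or Htt (227 kept) were named like the others, with their position.

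Total counts ranged from 38.21 to 56.61 M. The precision this gives was checked on simulated data with changes planted in 200 of 20843 genes. For Q140 against WT, edgeR found 65.7% of the genes changed by 0.3 log2 units, 89.6% of those changed by 0.6 and 100% of those changed by 1.2, with 7 false calls. The simulated counts were drawn independently for each gene, with no GC trend and no outlying library. Changes were planted only in genes with a mean log2 CPM of at least 0. The shares found in the real data may therefore be lower. No pair among 170 pairs of libraries of the same group was identical. The replicate numbers in the labels do not pair the libraries: within sex, libraries of the same number had a mean correlation of -0.0211 against 0.00273 for others (p = 0.344, 10000 permutations). Libraries sharing a number within the sample name, 25 numbers in all, had a mean correlation of 0.0325 against -0.00139 (p = 1e-04, the smallest these permutations can give). What that number stands for is not given, so it was used in an alternative only.

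The alternatives planned were DESeq2 1.42.0 (Wald test), DESeq2 size factors, no sex term, no low-count filter (37505 genes), a stricter filter of 10 counts in 24 libraries (19485 genes), only the libraries compared, a replicate block, the well column as a factor, limma-voom with the name number as a correlated group, limma on deposited FPKM with 0.1 or 1 added before the log, genes within 10 Mb of Mlh1 or Htt left out, and leaving out each library in turn. After the data were seen, more were added: each library left out of the gene list tests in turn, DESeq2's p-values adjusted over all genes with a p, the GC trend of each library removed, the 2 libraries lowest on the second principal component (Q140 female replicates 1 and 3) left out, both together, and the 3 libraries high in choroid plexus transcripts (Mlh1het female replicates 1 and 5 and Mlh1ko male replicate 1) left out. No deposited sample was left out of the comparisons otherwise.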

Results

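RNA from the cerebral cortex of 48 mice aged 4 months was sequenced. The Q140 knock-in allele, a mouse huntingtin gene (Htt) carrying an expanded CAG repeat as in Huntington's disease, was combined with disrupted alleles of Mlh1, a DNA mismatch repair gene. The 6 genotypes were WT (8 mice), Q140 (heterozygous for the knock-in, 7 mice), Mlh1het (1 disrupted Mlh1 allele, 9 mice), Mlh1ko (no intact Mlh1 allele, 7 mice), and the knock-in combined with either Mlh1 genotype, written Q140_Mlh1het (8 mice) and Q140_Mlh1ko (9 mice). Females and males numbered 24 each, and both sexes were present in every genotype. Total counts per library ranged from 38.21 to 56.61 M with a median of 44.76 M. The mean total was 45.7 M ± 3.43 (SD, n = 8) in WT, 47.9 ± 7.22 (n = 7) in Q140, 44.4 ± 3.46 (n = 9) in Mlh1het, 45.1 ± 2.71 (n = 8) in Q140_Mlh1het, 43.95 ± 2.81 (n = 7) in Mlh1ko and 43.3 ± 3.79 (n = 9) in Q140_Mlh1ko. Each library came from a separate mouse of its group as the labels name them, and no pair of same-group libraries among 170 agreed within sampling noise.

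The targeted genes were examined in every library. Mlh1 (ENSMUSG00000032498, chromosome 9, 111228228 to 111271791, minus strand, GRCm38) encodes a partner of the MutL mismatch repair complexes. Its level was 3.52 ± 0.281 log2 CPM (SD, n = 8, range 3.11 to 3.81) in WT and 3.43 ± 0.302 (n = 7, 3.06 to 3.91) in Q140. It was 2.87 ± 0.356 (n = 9, 2.04 to 3.29) in Mlh1het and 2.75 ± 0.439 (n = 8, 1.97 to 3.15) in Q140_Mlh1het. It was 1.77 ± 0.149 (n = 7, 1.60 to 1.96) in Mlh1ko and 1.69 ± 0.328 (n = 9, 1.28 to 2.26) in Q140_Mlh1ko. The difference from WT was -0.66 log2 units in Mlh1het (two-sided exact permutation test, p = 0.000617, adjusted p = 0.00103 over 15 pairs of genotypes) and -1.75 in Mlh1ko (exact permutation p = 0.000155, adjusted p = 0.000465). The difference between Q140_Mlh1ko and Q140 was -1.74 (exact permutation p = 8.74e-05, adjusted p = 0.000328). Reads remained over the gene in Mlh1ko, at a mean of 3.43 CPM against 11.7 CPM in WT. All 16 libraries without an intact allele lay below every WT and Q140 library. The libraries labelled Mlh1het female replicate 2 (2.04), Q140_Mlh1het female replicate 2 (1.97) and Q140_Mlh1het male replicate 3 (2.15) lay inside the range of the Q140_Mlh1ko libraries and above the highest Mlh1ko library. Htt (ENSMUSG00000029104, chromosome 5, 34761740 to 34912534, plus strand) had group means between 7.53 and 7.65 log2 CPM. No pair of genotypes differed in Htt after adjustment over 15 pairs, the smallest adjusted p being 0.0802 (exact permutation tests). Q140 was 0.052 log2 units above WT (exact permutation p = 0.178).

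**Figure D1:**
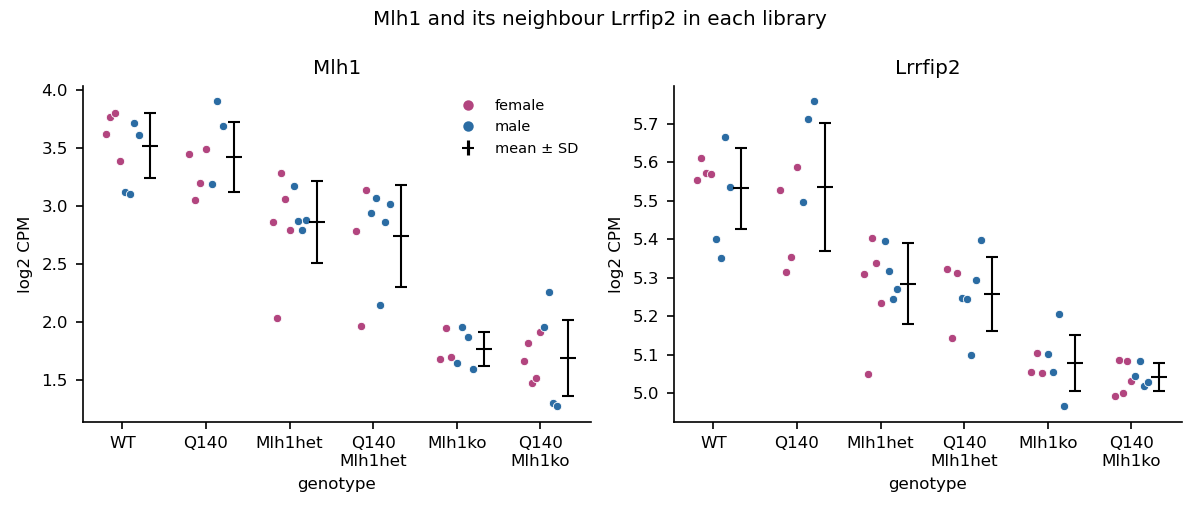
Expression of Mlh1 and of its neighbour Lrrfip2 in log2 CPM (vertical axes) in each of the 48 libraries by genotype (horizontal axes), with females and males in different colours and the mean ± SD of each group beside the points. Mlh1 averaged 3.52 in WT, 2.87 in Mlh1het and 1.77 in Mlh1ko, and Lrrfip2 averaged 5.53, 5.29 and 5.08 in the same groups.

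The effect of the knock-in with Mlh1 intact was measured by Q140 against WT (7 and 8 mice). The mRNAs encoded by the mitochondrial genome, all subunits of the respiratory chain and ATP synthase, had 13 of 13 fold changes below 0 and a median log2 fold change of -0.26 (preset adjusted p 1.25e-11, adjusted p = 0.462 with an estimated correlation). mt-Nd2 was at -0.34 (SE 0.102) and mt-Nd1 at -0.30. Genes of myelinating oligodendrocytes had 23 of 23 fold changes below 0 with a median of -0.21, among them Ugt8a, an enzyme of myelin galactolipid synthesis, at -0.29 (SE 0.12), Tspan2 at -0.22 and Trf, the iron carrier transferrin, at -0.27. Genes of activated microglia had 17 of 17 below 0 (median -0.19), led by the tetraspanin Cd9 at -0.42 (SE 0.11, 7 of 7 libraries below the WT mean). Genes induced by glucocorticoids lay the other way, with 15 of 18 above 0 and a median of 0.21, Plin4, a lipid droplet coat protein, standing at 0.97 (SE 0.353). No member of these lists passed over all genes, and no list passed with an estimated correlation. Adjusted over the list alone, 8 mitochondrial mRNAs, Cd9 and none of the myelin or glucocorticoid genes passed.

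No gene passed an adjusted p of 0.05 between Q140 and WT by edgeR's quasi-likelihood test among 20843 genes (smallest adjusted p 0.168), where 2074 genes (9.95%) had an unadjusted p under 0.05. DESeq2 called 27 after its own filter left 15358 genes without an adjusted p, and 2 when its p-values were adjusted over all 20820 genes with a p, a count added after the data were seen. The smallest p belonged to Cad (ENSMUSG00000013629), which encodes the enzyme of the opening steps of pyrimidine synthesis, at 0.28 (SE 0.0572, higher in 7 of 7 libraries), Ppp1cb, a catalytic subunit of protein phosphatase 1, at -0.15 (SE 0.0324, lower in 7 of 7), and the processed pseudogene Gm5853 at -0.63 (SE 0.134). Cad and Ppp1cb lie on chromosome 5, 3.68 and 2.24 Mb from Htt. Of 49 gene lists, 14 passed camera with the preset correlation, 1 of them upward, and 0 passed with an estimated correlation. The adjusted p for the mitochondrial mRNAs was 1.25e-11 with the preset correlation, and adjusted p = 0.462 with an estimated correlation. For the myelin genes these values were 4.84e-06 and adjusted p = 0.78 with an estimated correlation, for activated microglia 0.00122 and adjusted p = 0.643 with an estimated correlation, and for the glucocorticoid genes 0.00623 and adjusted p = 0.78 with an estimated correlation. The other lists past the preset test, all downward, were chaperones of the heat shock response (median -0.056, 29 of 31 below 0, adjusted p = 0.629 with an estimated correlation), the unfolded protein response (-0.073, 29 of 32, adjusted p = 0.643 with an estimated correlation), interferon-stimulated genes (-0.12, 28 of 34, adjusted p = 0.78 with an estimated correlation), astrocytes (-0.055, 15 of 20, adjusted p = 0.78 with an estimated correlation), microglia (-0.091, 18 of 21), pericytes (-0.11, 12 of 15), GABA receptors (-0.038, 13 of 15), histones (-0.12, 5 of 7) and clustered protocadherins (-0.040, 27 of 41), each of these last 5 with an adjusted p = 0.78 with an estimated correlation, and meninges (-0.16, 17 of 18, adjusted p = 0.792 with an estimated correlation). Among their members, Gja1 and Aqp4, the gap junction protein and water channel of astrocytes, passed adjusted over the list alone at -0.20 and -0.21, as did the endoplasmic reticulum chaperone Hsp90b1. In Mlh1ko against the same WT libraries, with no knock-in, some of the 14 lists also passed the preset test downward. Preset adjusted p there were 0.00203 for chaperones, 0.00807 for the unfolded protein response, 0.00325 for myelin and 0.00239 for pericytes. They were 0.000326 for microglia, 0.0336 for activated microglia and 3.48e-06 for meninges. Whether these calls reflect the knock-in or the shared WT libraries was not tested. The rest of the 14 did not pass there. Without Q140 male replicate 1, edgeR called 2 genes. Leaving out 1 library at a time ended the preset call of the glucocorticoid, interferon, microglia, pericyte, meninges, GABA receptor, protocadherin and histone lists in at least 1 case each. Without Q140 female replicate 1 the count of lists was 9 and the astrocyte median -0.025. Without WT female replicate 1 the microglia median was -0.036 (preset adjusted p 0.507) and the interferon median -0.071. Without WT male replicate 2 the medians were -0.062 for pericytes and -0.047 for the unfolded protein response. Without Q140 female replicates 1 and 3, 7 of the 14 lists kept their preset call, and those of activated microglia (0.0668), protocadherins (0.066), meninges (0.175), histones (0.272), astrocytes (0.295), pericytes (0.361) and microglia (0.378) were lost.

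Libraries differed in their share of mitochondrial mRNAs and in their trend with transcript GC content. Whether either moved with genotype was not tested beyond the gene list tests of the mitochondrial mRNAs, and whether the mitochondrial share is technical was not tested. The Q140 libraries with the most counts, female replicates 2 and 4 and male replicate 3, held 7.27%, 6.88% and 7.99%. Female replicate 3, at 45.11 M, held 7.62%. Mitochondrial mRNAs took 8.26% ± 1.12 (SD, n = 7) of the counts in Q140 and 9.62% ± 0.447 (n = 8) in WT, with all libraries between 6.88% and 11.4%. The Spearman correlation of the fold change with transcript GC content across 12335 genes was 0.394 for Q140 against WT, 0.41 for Mlh1het against WT, -0.47 for Q140_Mlh1het against Q140, -0.364 for Q140_Mlh1ko against Q140, and 0.0196 for Mlh1ko against WT. Genes are not independent replicates, so these values describe the libraries. Within Q140 the library trends ran from -0.327 in female replicate 1 to 0.457 in female replicate 2. Within WT they ran from -0.282 in male replicate 1 to 0.25 in female replicate 4. With the GC trend of each library removed, a step added after the data were seen, the mitochondrial mRNAs had a median of -0.21 and the myelin genes of -0.19 between Q140 and WT, while GABA receptors (median -0.0097, preset adjusted p 0.227) and protocadherins (-0.034, preset adjusted p 0.0591) no longer passed. Q140 female replicates 1 and 3 lay lowest on the second principal component, which held 6.69% of the variance.

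**Figure D2:**
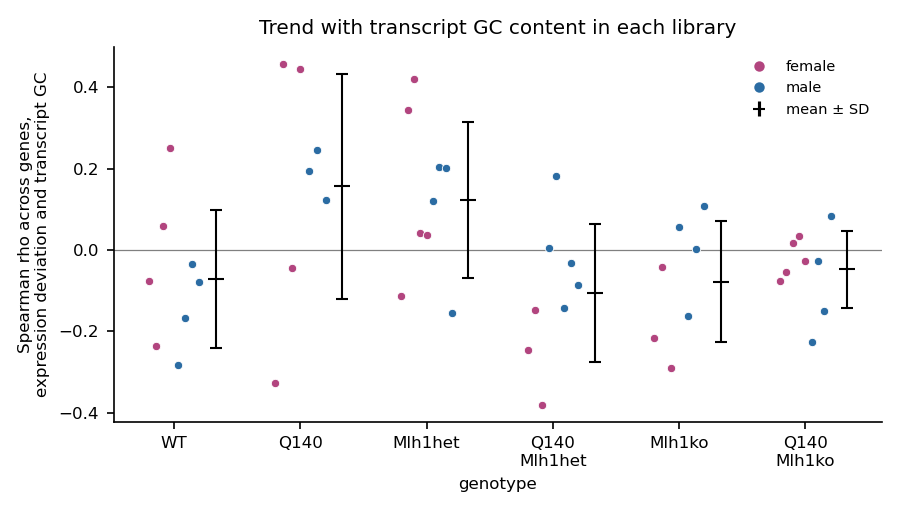
Spearman correlation across genes between each gene's deviation from its mean over the libraries and its transcript GC content (vertical axis) for each of the 48 libraries by genotype (horizontal axis), with females and males in different colours and the mean ± SD beside them. The Q140 libraries span -0.327 to 0.457, and the Q140_Mlh1ko libraries span -0.226 to 0.0841.

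Averaging the knock-in effect over the 3 Mlh1 genotypes compared 24 knock-in mice with 24 mice without it. Of 11 genes past the threshold, 9 lay within 10 Mb of Htt on chromosome 5. Cad rose by 0.21 log2 units (SE 0.0322, adjusted p = 0.00064, 22 of 24 libraries above the control mean). Drc1, a component of the dynein regulatory complex of motile cilia, rose by 0.27 (SE 0.0424, adjusted p = 0.00064, 23 of 24). Mrpl33, a mitochondrial ribosomal protein, rose by 0.19 (SE 0.0329, adjusted p = 0.00164, 23 of 24), and Prr14l rose by 0.12 (SE 0.0255, adjusted p = 0.0482, 20 of 24). Atraid fell by 0.24 (SE 0.0397, adjusted p = 0.00111, 22 of 24 lower) and Ppp1cb fell by 0.097 (SE 0.0182, adjusted p = 0.00808, 20 of 24 lower). Their positions on chromosome 5 (GRCm38) were 31054780 to 31078479 for Cad, 30281388 to 30366695 for Drc1, 31596935 to 31664384 for Mrpl33, 32789820 to 32854256 for Prr14l, 31048312 to 31054623 for Atraid and 32458843 to 32517433 for Ppp1cb, at 1.91 to 4.4 Mb from Htt. The other 5 genes were low in expression and were chosen after their values were seen. Abhd1 (1.14, SE 0.18, adjusted p = 0.00064), the pseudogene Gm2420 (0.87) and Gm43693 (0.46) lie 3.81, 2.03 and 1.78 Mb from Htt, while the noncoding RNAs Lncpint (0.55, chromosome 6) and Macrod2os1 (1.001, chromosome 2, antisense) lie elsewhere. The strand setting of the counts is not given in the sources used here, so the assignment of reads to the antisense gene is uncertain. With the well column as a factor Prr14l (adjusted p = 0.148), Lncpint (adjusted p = 0.12) and Gm43693 (adjusted p = 0.13) did not pass, and with a replicate block Prr14l did not (adjusted p = 0.058). With the name number as a correlated group Lncpint did not pass (adjusted p = 0.13), nor with no sex term (0.0725) or on FPKM with 0.1 or 1 added (0.0802 and 0.0759). Prr14l did not pass with DESeq2 size factors (0.0528), Prr14l and Gm43693 did not with no low-count filter (0.0702 and 0.0539), and Macrod2os1 did not on FPKM with 1 added (0.0604). Without Q140 female replicates 1 and 3, a setting added after the data were seen, 7 genes passed, all within 10 Mb of Htt. Lncpint and Macrod2os1 were therefore not among them. Htt itself was at -0.022 (SE 0.0188) and Mlh1 at -0.084 (SE 0.0891), neither passing.

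**Figure D3:**
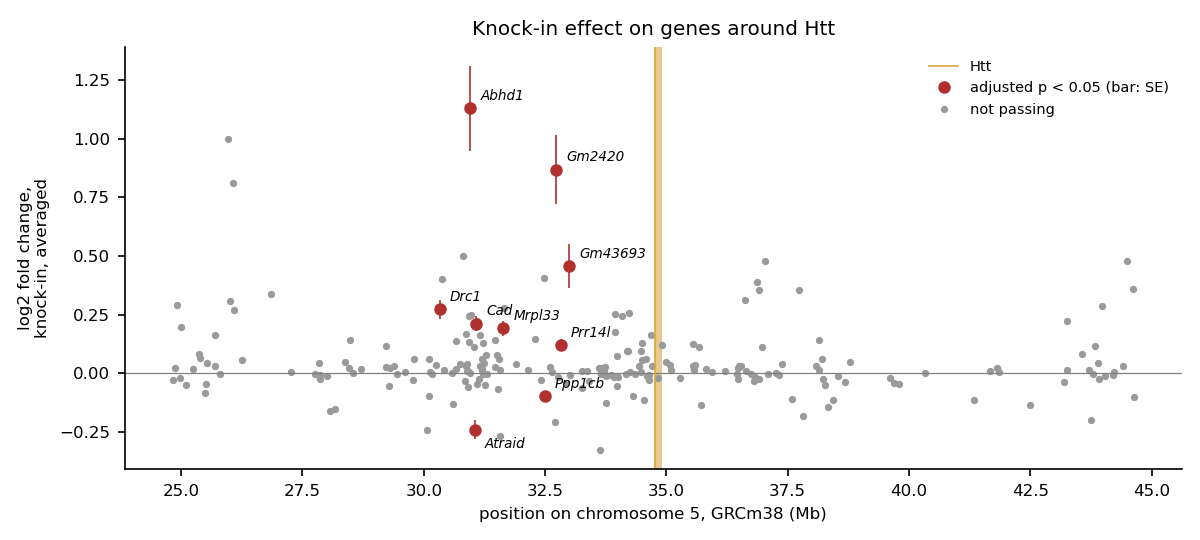
Log2 fold change of the knock-in averaged over Mlh1 genotypes (vertical axis) for each tested gene against its position on chromosome 5 in Mb of GRCm38 (horizontal axis), within 10 Mb of Htt, whose span is shaded. The 9 genes with an adjusted p under 0.05 are named and carry their SE; the farthest, Drc1, lies 4.4 Mb from Htt.

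Among the gene lists, myelinating oligodendrocyte genes had 23 of 23 averaged knock-in fold changes below 0 with a median of -0.16. Tspan2 was at -0.18 (SE 0.0483), Ugt8a at -0.24 and Plp1, the main protein of central myelin, at -0.23. None passed over all genes, and Plp1, Ugt8a, Fa2h and Tspan2 passed adjusted over the list alone. The preset camera test gave an adjusted p of 5.63e-15, and adjusted p = 0.454 with an estimated correlation. Genes of cholesterol biosynthesis had 24 of 26 below 0 (median -0.057, with the sterol regulator Insig1 at -0.16 and Idi1 at -0.13), and glucocorticoid-induced genes had 16 of 18 above 0 (median 0.12), where Plin4 at 0.72 (SE 0.207) and the sulfotransferase Sult1a1 at 0.31 passed adjusted over the list alone. Both lists had a preset adjusted p of 1.94e-06 and adjusted p = 0.454 with an estimated correlation. Choroid plexus genes, which mark tissue of the ventricle rather than the cortex, had a median of -1.30 (preset adjusted p 7.1e-06, adjusted p = 0.454 with an estimated correlation) with Ttr at -3.47, and 3 control libraries held high levels of them. Without Mlh1ko male replicate 1 the median was -0.34, and without all 3 libraries the list no longer passed (preset adjusted p 0.576). Mitochondrial mRNAs (-0.084, 13 of 13 below 0), heat shock chaperones (-0.027, 28 of 31), neuropeptides (-0.071, 17 of 20), oligodendrocyte precursors (-0.040, 12 of 15) and GABA receptors (-0.018, 14 of 15) passed the preset test downward, each with an adjusted p = 0.454 with an estimated correlation. Gabra2, a GABA-A receptor subunit, at -0.27 (SE 0.084), passed adjusted over its list alone. Deep-layer excitatory neurons (-0.071, 18 of 19, adjusted p = 0.469 with an estimated correlation), ribosomal proteins (-0.020, 31 of 40, adjusted p = 0.571 with an estimated correlation), the unfolded protein response (-0.025, 28 of 32, adjusted p = 0.554 with an estimated correlation), astrocytes (-0.026, 15 of 20, adjusted p = 0.583 with an estimated correlation) and synaptic vesicle genes (-0.019, 24 of 33, adjusted p = 0.46 with an estimated correlation) completed the 14. DESeq2 called 19 genes, including the same 11. Medians moved to 0.079 for the glucocorticoid genes and -0.030 for ribosomal proteins without Q140_Mlh1ko female replicate 5, to -0.012 for GABA receptors without Q140_Mlh1het male replicate 2 (preset adjusted p 0.0586, the call being lost in 3 removals) and to -0.017 for astrocytes without Q140_Mlh1het male replicate 1 (0.0563, also lost). The synaptic vesicle call was lost in 5 removals (largest preset adjusted p 0.0931, without Q140_Mlh1het male replicate 2), and with the GC trend removed GABA receptors no longer passed (preset adjusted p 0.0508). Without Q140 female replicates 1 and 3 the synaptic vesicle (0.0559) and astrocyte (0.0741) lists did not pass. The count of genes was 7 without Q140 female replicate 1, without Q140_Mlh1ko male replicate 1 or without Mlh1ko female replicate 1.

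The knock-in effect was also measured within each Mlh1 background. Between Q140_Mlh1het and Mlh1het (8 and 9 mice), the smallest p belonged to the noncoding Gm43625 (-1.09, SE 0.23), Drc1 (0.32, SE 0.0711, higher in 8 of 8 libraries) and Atraid (-0.30, SE 0.0673, lower in 8 of 8), none passing. Cholesterol biosynthesis genes had 24 of 26 fold changes below 0 (median -0.069, Mvk at -0.14), neuropeptides 18 of 20 (median -0.096, chromogranin A, Chga, at -0.18) and myelin genes 20 of 23 (median -0.11), with preset adjusted p of 2.04e-05, 0.00106 and 0.000789 and adjusted p = 0.744, 0.645 and 0.833 with an estimated correlation. Genes of striatal projection neurons had 29 of 33 below 0 (median -0.095), with the transcription factor Six3 at -2.36 (SE 0.791) and the adenosine receptor Adora2a at -1.02 (adjusted p = 0.744 with an estimated correlation). Without Mlh1het female replicate 1 this median was -0.0032 and the preset adjusted p 0.974, and the myelin list no longer passed either (preset adjusted p 0.137). Glucocorticoid-induced genes had 16 of 18 above 0 (median 0.16, or 0.069 and past no threshold without Q140_Mlh1het female replicate 1, adjusted p = 0.744 with an estimated correlation). Without Mlh1het female replicate 5 the neuropeptide median was -0.062. Altogether 8 lists passed the preset test and 0 with an estimated correlation. No gene passed by edgeR or by DESeq2, with 899 genes at an unadjusted p under 0.05. Without Mlh1het male replicate 3, edgeR called 3 genes.

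Between Q140_Mlh1ko and Mlh1ko (9 and 7 mice), genes of the choroid plexus had the smallest p, with the prolactin receptor Prlr at -2.37 (SE 0.499), the thyroxine carrier Ttr at -6.64 (SE 1.45) and coagulation factor F5 at -3.35 (SE 0.735), none passing. The mean log2 CPM of the choroid plexus list was 4.96 in Mlh1ko male replicate 1 and at most 0.52 in the other Mlh1ko libraries. Reactive astrocyte genes had 21 of 22 fold changes above 0 (median 0.31, Timp1 at 0.98, SE 0.313), meningeal genes 17 of 18 (median 0.23) and pericyte genes 15 of 15 (median 0.12). Myelin genes had 23 of 23 below 0 (median -0.16) and deep-layer neuron genes 16 of 19 (median -0.17). The adjusted p was 0.576 with an estimated correlation for the myelin genes and 0.478 with an estimated correlation for the other 4 lists. The meningeal mean was 2.22 log2 CPM in Mlh1ko male replicate 4 and 3.17 or more in the other Mlh1ko libraries. Without that library the meningeal median was 0.11 (preset adjusted p 0.0504) and 9 lists passed. Without Q140_Mlh1ko female replicate 5 the medians were 0.093 for reactive astrocytes (preset adjusted p 0.113) and 0.067 for pericytes. Without Mlh1ko male replicate 2 they were -0.097 for myelin and -0.097 for deep-layer genes, both lists still passing. The choroid plexus median of -2.39 (preset adjusted p 4.71e-07, adjusted p = 0.478 with an estimated correlation) was -0.057 without Mlh1ko male replicate 1. In all, 16 lists passed the preset test and 0 with an estimated correlation. No gene passed by edgeR (951 with an unadjusted p under 0.05), and DESeq2 called 1.

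Loss of Mlh1 without the knock-in was measured by Mlh1ko against WT (7 and 8 mice). Mlh1 fell by 1.78 log2 units (SE 0.164, adjusted p = 3.7e-10, lower in 7 of 7 libraries). Lrrfip2 (ENSMUSG00000032497, chromosome 9, 111117592 to 111225668, plus strand), which encodes an adaptor of Wnt and Toll-like receptor signalling, fell by 0.46 (SE 0.0525, adjusted p = 2.09e-07, lower in 7 of 7). The gene ends 0.00256 Mb from the end of Mlh1 and is transcribed toward it. The strand setting of the deposited counts is not given in the sources used here, so which strand these reads came from is uncertain. No other gene passed among 20843, and 632 (3.03%) had an unadjusted p under 0.05. No other mismatch repair gene passed, with Pms2, the partner of Mlh1 in MutLα, at 0.054 (SE 0.0466) and Pold2 at -0.062. Choroid plexus genes had 10 of 11 fold changes above 0 with a median of 2.58, 9 of them past adjusted over the list alone (Ttr at 7.25, SE 1.49), in a group where 1 library, male replicate 1, held these transcripts at a mean of 4.96 log2 CPM. The list had a preset adjusted p of 3.48e-06, and adjusted p = 0.941 with an estimated correlation. Without male replicate 1 its median was -0.019, and without all 3 libraries high in these transcripts the list no longer passed (preset adjusted p 0.927). Immediate early genes had 26 of 31 above 0 (median 0.23, Klf10 at 0.43, adjusted p = 0.95 with an estimated correlation). Microglial genes had 19 of 21 below 0 (median -0.076, Ctss at -0.12, adjusted p = 0.941 with an estimated correlation), and meningeal genes 16 of 18 (median -0.20, adjusted p = 0.941 with an estimated correlation). Mlh1ko male replicate 4 carried much of the meningeal and immediate early values: its meningeal mean was 2.22 log2 CPM against 3.17 or more in the other Mlh1ko libraries, and without it the medians were -0.11 (preset adjusted p 0.287) and 0.075 (preset adjusted p 0.285). The immediate early list also did not pass without the 3 libraries high in choroid plexus transcripts (0.0526). Without WT female replicate 1 the microglial median was -0.039 (preset adjusted p 0.249). Also past the preset test, downward, were reactive astrocytes (median -0.177), pericytes (-0.092) and activated microglia (-0.135). Heat shock chaperones (-0.031), the unfolded protein response (-0.047) and myelin (-0.089) passed it downward too. The myelin list did not pass without the 3 libraries high in choroid plexus transcripts (0.0526). In all, 10 lists passed the preset test and 0 with an estimated correlation, where the smallest adjusted p was 0.941. DESeq2 called 4 genes. The edgeR count was 7 without Mlh1ko female replicate 1, 5 without female replicate 2 or female replicate 3, 6 without male replicate 3 and 4 without male replicate 2.

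Loss of Mlh1 in knock-in mice was measured by Q140_Mlh1ko against Q140 (9 and 7 mice). Mlh1 fell by 1.74 (SE 0.155, adjusted p = 1.1e-10) and Lrrfip2 fell by 0.50 (SE 0.0505, adjusted p = 3.94e-09), both lower in 9 of 9 libraries. No other gene passed, and 2094 genes had an unadjusted p under 0.05. Interferon-stimulated genes had 31 of 34 fold changes above 0 with a median of 0.27, and 9 of them passed adjusted over the list alone. Among these were Trim30a (0.37, SE 0.118), Oasl2 (0.39, SE 0.125, above the Q140 mean in 8 of 9 libraries) and Ifit2, an RNA-binding antiviral protein (0.17, SE 0.0539, 9 of 9). The preset camera test gave an adjusted p of 1.9e-09, and adjusted p = 0.56 with an estimated correlation. Mitochondrial mRNAs had 13 of 13 above 0 (median 0.20, mt-Co2 at 0.29, preset adjusted p 5.62e-09, adjusted p = 0.56 with an estimated correlation), beside the lower share of these mRNAs in the Q140 libraries given above. Nuclear genes of oxidative phosphorylation had 36 of 41 below 0 (median -0.045, Sdhd at -0.15, adjusted p = 0.575 with an estimated correlation).

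Vascular genes stood with them. Endothelial genes had 16 of 19 fold changes above 0 (median 0.13), and Slco1c1 (0.20), the receptor Kdr (0.42, SE 0.139), Cdh5 (0.21), Emcn and Mfsd2a passed adjusted over the list alone in the Q140_Mlh1ko and Q140 comparison. Pericyte genes had 14 of 15 above 0 (median 0.12, Vtn at 0.18, SE 0.0545, 9 of 9 libraries), reactive astrocyte genes 17 of 22 (median 0.30, Ggta1 at 0.34 and complement C4b at 0.78, SE 0.278) and activated microglia genes 16 of 17 (median 0.21, Cd68 at 0.24), each of these 4 lists with an adjusted p = 0.575 with an estimated correlation. Meningeal genes had 18 of 18 above 0 (median 0.18, adjusted p = 0.656 with an estimated correlation), and glucocorticoid-induced genes 15 of 18 below 0 (median -0.16, Plin4 at -1.08, adjusted p = 0.749 with an estimated correlation). Without Q140_Mlh1ko female replicate 5 the medians were 0.057 for reactive astrocytes (preset adjusted p 0.581), 0.069 for activated microglia (preset adjusted p 0.176), 0.080 for endothelial cells (preset adjusted p 0.103) and -0.32 for the glucocorticoid genes. Without Q140_Mlh1ko male replicate 4 the meningeal list no longer passed (preset adjusted p 0.0547), and without Q140 female replicate 1 the glucocorticoid list did not (preset adjusted p 0.198). The protocadherin call was lost in 3 removals, with a preset adjusted p of up to 0.137 (without Q140 male replicate 1). Of the clustered protocadherins, cell adhesion genes of neuronal identity, 29 of 41 lay above 0 (median 0.027, or 0.0090 and past no threshold without Q140_Mlh1ko male replicate 2, adjusted p = 0.575 with an estimated correlation), and Pcdha1 (0.52, SE 0.114, 9 of 9 libraries), Pcdha8 (0.77, SE 0.188) and Pcdhgc3 (0.16) passed adjusted over the list alone, none over all genes. With an estimated correlation 0 of the 10 lists passed. Without Q140 female replicates 1 and 3, a setting added after the data were seen, 3 of these 10 lists kept their preset call: interferon-stimulated genes (2.44e-05), mitochondrial mRNAs (5.2e-05) and nuclear oxidative phosphorylation (7.8e-10). Lost were endothelial cells (0.218), pericytes (0.184), activated microglia (0.173), reactive astrocytes and meninges (both 0.0943), protocadherins (0.0701) and glucocorticoid-induced genes (0.0566). Reactive astrocytes also did not pass with a replicate block (0.13). DESeq2 called 15 genes with 5667 left unadjusted, and 14 when adjusted over all genes with a p, and edgeR called 15 without Q140 female replicate 1, 8 without Q140 female replicate 3 and 4 without Q140_Mlh1ko male replicate 2. Without both of those Q140 females the count was 207, of which Mlh1 and Lrrfip2 were left when the GC trend was also removed.

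Averaging Mlh1 loss over the Htt genotypes set 16 mice without Mlh1 against 15 mice with both alleles. Mlh1 fell by 1.76 (SE 0.113, adjusted p = 5.25e-16) and Lrrfip2 fell by 0.48 (SE 0.0365, adjusted p = 2.03e-13), both lower in 16 of 16 libraries. Pcdha1, an alpha protocadherin, rose by 0.44 (SE 0.0818, adjusted p = 0.00631, 16 of 16). Nt5dc2 (chromosome 14, 31131053 to 31139124) rose by 0.48 (SE 0.0934, adjusted p = 0.0135, 16 of 16) and Gm14418 (chromosome 2, 177387124 to 177398320) rose by 0.57 (SE 0.0981, adjusted p = 0.00226, 15 of 16). Another 4 genes passed at low expression and were chosen after their values were seen. These were Tdgf1 (-1.62, chromosome 9, 110939603 to 110946158, 0.282 Mb from Mlh1), Pcdha8 (0.81, 15 of 16) and 1700030C10Rik, listed under 2 overlapping identifiers (1.69 and 1.60). The exons at the shared end of the protocadherin alpha cluster belong to several of its transcripts, so the split of reads between Pcdha1 and Pcdha8 is uncertain. With the well column as a factor, 4 of the 9 genes passed and 1 of them rose, Pcdha8, while Pcdha1 (adjusted p = 0.0622), Gm14418 (adjusted p = 0.0622), Nt5dc2 (adjusted p = 0.0965) and both 1700030C10Rik identifiers (adjusted p = 0.125) did not. With the name number as a correlated group the 1700030C10Rik identifiers did not pass either (adjusted p = 0.229 and 0.613), and ENSMUSG00000099759 did not on FPKM with 0.1 added (0.0924). Adjusted over the list alone, 4 of 41 protocadherins passed, with Pcdhb14 at -0.16 and Pcdhga7 beside the alpha members, against 2 over all genes. Of the lists, 9 passed the preset test and 0 with an estimated correlation, among them interferon-stimulated genes (30 of 34 above 0, median 0.099, adjusted p = 0.95 with an estimated correlation). In the comparisons behind this average the median was 0.27 in Q140_Mlh1ko against Q140 and -0.0016 in Mlh1ko against WT, where the list did not pass (16 of 34 above 0, preset adjusted p 0.713, adjusted p = 0.966 with an estimated correlation). Of all genes, 1316 had an unadjusted p under 0.05, and DESeq2 called 10, including the same 9.

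Loss of 1 Mlh1 allele was measured in both backgrounds. Between Mlh1het and WT (9 and 8 mice), Lrrfip2 was at -0.25 (SE 0.0488, adjusted p = 0.148) and Mlh1 at -0.65 (SE 0.142, adjusted p = 0.394), both lower in 9 of 9 libraries and neither passing over all genes. The receptor gene Gpr101 was next at 2.14 (SE 0.536). Genes of striatal projection neurons had 28 of 33 fold changes above 0 (median 0.14), with Six3 at 2.79 (SE 0.793, above the WT mean in 5 of 9 libraries, past adjusted over the list alone) and the dopamine receptor Drd2 at 1.40 (adjusted p = 0.664 with an estimated correlation). Without Mlh1het female replicate 1 the striatal median was 0.018 (preset adjusted p 0.783). Interneuron genes had 15 of 22 above 0 (median 0.062, Sst at 0.14 in 9 of 9 libraries), and heat shock chaperones had 30 of 31 below 0 (median -0.049, Dnaja1 at -0.11), both with an adjusted p = 0.664 with an estimated correlation. The interneuron call was lost in 5 removals, with a preset adjusted p of up to 0.146 (without Mlh1het female replicate 1), and with the GC trend removed (0.0966). With the preset correlation 6 lists passed, and 0 with an estimated one. No gene passed by edgeR (861 with an unadjusted p under 0.05, 1 called without WT male replicate 2), and DESeq2 called 1.

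Between Q140_Mlh1het and Q140 (8 and 7 mice), Lrrfip2 fell by 0.29 (SE 0.0521, adjusted p = 0.028, lower in 8 of 8 libraries), and Mlh1 was at -0.67 (SE 0.152, adjusted p = 0.34), also lower in 8 of 8. Lrrfip2 did not pass with a replicate block (-0.29, adjusted p = 0.0511), with the well column as a factor (adjusted p = 0.169) or with only the libraries compared (adjusted p = 0.64). Mitochondrial mRNAs had 13 of 13 fold changes above 0 (median 0.20), with mt-Co1 (0.19) and mt-Nd5 (0.24) past adjusted over the list alone, and nuclear oxidative phosphorylation genes 33 of 41 below 0 (median -0.037, Cyc1 at -0.14). Genes of the unfolded protein response had 27 of 32 above 0 (median 0.066, Hsp90b1 at 0.13), and those of pericytes 13 of 15 (median 0.14, Vtn at 0.22, SE 0.0561). Medians moved to 0.038 for the unfolded protein response without Q140_Mlh1het male replicate 1, to 0.085 for pericytes without Q140_Mlh1het female replicate 1 (preset adjusted p 0.0922) and to -0.070 for oxidative phosphorylation without Q140_Mlh1het female replicate 2. The pericyte call was lost in 5 such removals, with a preset adjusted p of up to 0.185 (without Q140 female replicate 1), and that of the unfolded protein response without Q140 male replicate 2 (0.0514). Without Q140 female replicates 1 and 3, 2 of the 10 lists kept their call, mitochondrial mRNAs and oxidative phosphorylation, and the unfolded protein response (0.217) and pericytes (0.456) did not. All these lists had an adjusted p = 0.814 with an estimated correlation, and 10 lists passed with the preset one, 3 without Q140 female replicate 1 or without Q140 male replicate 2. Of all genes, 1595 had an unadjusted p under 0.05 and DESeq2 called 2. The single call moved with 1 library at a time: 8 genes passed without Q140 female replicate 1 and 2 without Q140_Mlh1het male replicate 4, while 0 passed without Q140 female replicate 4, male replicate 2 or male replicate 3, or without Q140_Mlh1het female replicate 2, male replicate 1, male replicate 2 or male replicate 3.

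Averaged over the Htt genotypes, 17 mice with 1 intact Mlh1 allele were set against 15 with both. Lrrfip2 fell by 0.27 (SE 0.0357, adjusted p = 2.94e-05) and Mlh1 fell by 0.66 (SE 0.104, adjusted p = 9e-04), each lower in 17 of 17 libraries. No other gene passed, with 702 at an unadjusted p under 0.05, and DESeq2 called the same 2. Mitochondrial mRNAs had 13 of 13 above 0 (median 0.056), nuclear oxidative phosphorylation genes 36 of 41 below 0 (median -0.024), and both had an adjusted p = 0.853 with an estimated correlation. With the preset correlation 7 lists passed, and 0 without Q140_Mlh1het female replicate 3, where the mitochondrial median was 0.027. Without Q140 female replicates 1 and 3 the mitochondrial list did not pass (preset adjusted p 0.069). Without Q140 female replicate 4 the oxidative phosphorylation median was -0.014.

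Whether the knock-in effect differed between Mlh1 backgrounds was tested as an interaction. For 1 disrupted allele the genes with the smallest p were 1810014B01Rik (0.41, SE 0.0956), Htatsf1 (0.16) and the protease Pcsk7 (-0.24), and without intact Mlh1 they were Gm5853 (0.89, SE 0.186), Gm10135 (1.13) and Nlrp3, the inflammasome sensor (1.27, SE 0.288). None passed by edgeR, where 1818 and 1217 genes had an unadjusted p under 0.05, and DESeq2 called 0 in both. In the interaction without intact Mlh1, reactive astrocyte genes had 20 of 22 values above 0 (median 0.53, with Gfap at 1.88, SE 0.612, C4b and Ggta1 among the 4 past adjusted over the list alone), interferon-stimulated genes 29 of 34 (median 0.27, Oasl2 at 0.56), activated microglia genes 17 of 17 (median 0.39), meningeal genes 17 of 18 (median 0.34), pericyte genes 14 of 15 (median 0.19) and mitochondrial mRNAs 13 of 13 (median 0.26). These 6 lists had an adjusted p = 0.304 with an estimated correlation. Without Mlh1ko male replicate 4 the meningeal median was 0.20, and without Q140_Mlh1ko female replicate 5 the medians were 0.25 for reactive astrocytes and 0.18 for activated microglia, these lists still passing the preset test. With 1 disrupted allele, mitochondrial mRNAs had 12 of 13 above 0 (median 0.29), heat shock chaperones 27 of 31 (median 0.075, Dnaja1 at 0.18) and the unfolded protein response 29 of 32 (median 0.11, Hsp90b1 at 0.23), with an adjusted p = 0.66 with an estimated correlation for all 3. The preset test passed 11 lists in each interaction. The correlation of the interaction with transcript GC content across genes was -0.555 with 1 disrupted allele and -0.32 without intact Mlh1, and removing the trend took 1818 genes to 1010 and 1217 to 1101.

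The direction of the knock-in effect with and without Mlh1 was compared across genes. No gene passed in Q140 against WT, so the 200 genes with the smallest p there were used. Across these genes the fold changes of Q140 against WT and of Q140_Mlh1ko against Mlh1ko, which share no library, had a Pearson r of 0.704 and a Spearman rho of 0.301, with 69% on the same side of 0. Among 100 simulations of unchanged groups r averaged -0.0371 (SD 0.302), and 1 reached the observed value. The rho, lower than r, was not set beside simulated values. Genes near Htt, Cad and Ppp1cb among them, were kept in the 200, and r without them was not computed. Over all 20843 genes r was 0.173 and rho 0.0927. Against Q140_Mlh1ko minus Q140, which shares the Q140 libraries with opposite sign, r was -0.735 over the 200 genes, less negative than the mean of -0.877 with no effect, and the covariance was -0.0525 against a simulated -0.0827. With the Q140 libraries split between both comparisons the mean r over 70 splits was -0.0681 (range -0.529 to 0.716, below 0 in 45), with a mean rho of -0.228 and 33% on the same side of 0. Over all genes the mean r of these splits was 0.00849 (range -0.136 to 0.309, below 0 in 41), the mean rho -0.0703, and 45.5% lay on the same side. Genes are not independent replicates.

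Differences between the sexes in genotype effects were tested for 3 comparisons. For Q140_Mlh1ko against Q140 the male effect exceeded the female effect for Dgkh, a diacylglycerol kinase (chromosome 14, 78558750 to 78732776), by 0.75 log2 units (SE 0.11, adjusted p = 0.000454), and for Gucy1a2, a subunit of soluble guanylate cyclase (chromosome 9, 3532778 to 3894736), by 0.83 (SE 0.145, adjusted p = 0.0095). In this test 1755 genes had an unadjusted p under 0.05, and DESeq2 called 31, or 28 when adjusted over all genes with a p. It rests on 4 female and 3 male Q140 mice, of which female replicates 1 and 3 lay lowest on the second principal component. The sex differences were not refitted with any library left out. For Q140 against WT no gene passed by edgeR (1094 with an unadjusted p under 0.05), the smallest p being those of Tacc3 (0.70), Gucy1a2 (-0.65) and Rps19-ps3 (1.44). For Mlh1ko against WT no gene passed either (985 with an unadjusted p under 0.05), with Pgam2 (1.06), Nrip1 (-0.32) and Rbbp7 (-0.20) at the smallest p.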

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

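Of the tests in this part, those of a regional cause near Htt, of the genes nearest Htt, of shared reads at Lrrfip2, of proportion to alleles of the fold changes behind the calls without Q140 female replicates 1 and 3, and of the gene counts of the knock-in comparisons under other splits were chosen after the result was seen. Within groups of 7 to 9 libraries, 42 pairs of a group and a measure were checked for a sample far from the others, and 5 were found, where chance gives about 1 in 20. Total counts of WT male replicate 2 were 53.66 M, the next being 46.66. The mean log2 CPM of choroid plexus genes was 3.17 in Mlh1het female replicate 5 (next 1.18) and 4.96 in Mlh1ko male replicate 1 (next 0.52). In Mlh1het female replicate 2, Mlh1 was at 2.04 log2 CPM (next 2.80) and Lrrfip2 at 5.05 (next 5.24). No cause was tested for these. The sex difference of Q140_Mlh1ko against Q140 passed its own test for Dgkh (0.75) and Gucy1a2 (0.83).

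Genes called near Htt in the averaged knock-in comparison made up 9 of 11 calls (81.8%), against 227 of 20843 tested genes (1.09%). A genome-wide response without a regional cause is argued against by this share as the source of these calls (Fisher's exact p = 9.93e-17). The test treats genes as independent, which neighbouring genes measured in the same mice are not, so its p is too small. A wider response beside a regional one is not excluded. Strain DNA carried along with the knock-in allele could give such a region, and fold changes near Htt in independent libraries had a rho of 0.221 over 226 genes, where 10 of 74 runs of genes elsewhere were as high, so it cannot be told apart from other causes. An effect of the altered allele limited to genes within 1 Mb is argued against for these calls, since the nearest called gene lies 1.78 Mb away and 0 of the 41 genes within 1 Mb passed. This test by distance replaced an earlier one by share, after that had not decided: 14.6% of genes within 1 Mb had an unadjusted p under 0.05, against 20% from there to 10 Mb (Fisher's exact p = 0.515). Elsewhere the share was 7.01% (1445 of 20616 genes), so changes short of the threshold in the genes within 1 Mb are not excluded. An effect of the allele reaching farther was not tested.

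Lower Lrrfip2 where Mlh1 was lost was seen in every comparison that removed an Mlh1 allele, passing over all genes in 5 of 6. Whether reads of Mlh1 transcripts counted for Lrrfip2 contribute was not decided. The fall of 12.6 CPM (SE 1.33) was 1.08 times the Mlh1 CPM of WT, too near that level to lie clearly above or below it. Reads counted for Lrrfip2 are not part of the Mlh1 count, so that level does not bound them. Mlh1ko kept a mean of 3.43 CPM over Mlh1, so fewer Mlh1 reads were lost than that WT level. Without the strand setting, a part of the fall from such reads cannot be told apart from a fall of Lrrfip2 itself. Linked strain DNA may also contribute, as fold changes of the other genes near Mlh1 in independent libraries had a rho of 0.166 over 275 genes, and 1 of 62 runs elsewhere was as high. The fall with 1 disrupted allele was 0.595 of that with both (95% bootstrap interval 0.473 to 0.706), in line with a change in proportion to alleles, which linked DNA and shared reads predict as well. The difference is a hypothesis in its cause.

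Leaving out Q140 female replicates 1 and 3 gave 207 calls in Q140_Mlh1ko against Q140 in place of 2. Leaving out any 2 Q140 libraries is argued against, since 1 of 21 pairs gave as many and the next highest gave 18. The GC trend of the libraries may account for part of it, because 2 genes were called with these libraries left out and the trend removed. Over the 205 genes other than Mlh1 and Lrrfip2, the median size of the fold change went from 0.18 (median SE 0.0441) to 0.13 (median SE 0.0415) with the trend removed, so the calls ended as the fold changes shrank, and 186 of them kept an unadjusted p under 0.05. The genes were picked for passing before the trend was removed, which by itself favours a smaller value after. An effect of Mlh1 loss with or without the knock-in may also take part: 60.5% of these genes lay on the same side of 0 in Mlh1ko against WT, barely above the bound of 60% set for it, with genes that are not independent. The share over all genes was not set beside it. In Q140 against WT of all libraries, 91.2% of these genes lay on the opposite side, which the shared Q140 libraries by themselves favour.

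Other splits of the samples tested whether chance can be excluded for each count of genes, with 100 splits each. It can for the averaged knock-in effect (11 genes, 1 split as large, the real one, highest other 8), Mlh1ko against WT (2 genes, 1 split, highest other 1), the averaged Mlh1ko effect (9 genes, 2 splits, highest other 33), Q140_Mlh1het against Q140 (1 gene, 4 splits, highest other 4) and the averaged Mlh1het effect (2 genes, 2 splits, highest other 2). The calls of Mlh1ko against WT and of the averaged Mlh1het effect were Mlh1, whose alleles define the groups, and its neighbour Lrrfip2, and the call of Q140_Mlh1het against Q140 was Lrrfip2, so these counts say nothing about a response elsewhere. Of the 11 genes of the averaged knock-in effect, 9 lie within 10 Mb of Htt, whose knock-in allele defines those groups. The splits were not compared for the 2 genes elsewhere, so chance is not excluded for those. The averaged Mlh1ko count also holds Mlh1 and Lrrfip2. The splits were not compared for the 6 of its genes that lie over 10 Mb from Mlh1 and Htt, so chance is not excluded for those. Chance is not excluded for the count of Q140_Mlh1ko against Q140 (2 genes, 5 splits, highest other 47). This concerns the count alone: both calls are Mlh1 and Lrrfip2, lower in 9 of 9 libraries (adjusted p = 1.1e-10 and 3.94e-09; Mlh1 exact p = 8.74e-05), so chance is not open for these genes, and their count says nothing about a response elsewhere. Where the real count was 0, all 100 splits give as many by construction, so these say nothing about chance. The highest other was 139 for Q140 against WT, 10 for Q140_Mlh1het against Mlh1het, 13 for Q140_Mlh1ko against Mlh1ko, 51 and 5 for the interactions with 1 and no intact allele, and 1 for Mlh1het against WT. Single splits with 139, 47 and 33 calls point to a structure of the samples, and what those splits align with was not tested. In 50 splits of the sexes, 2 gave as many genes for Q140_Mlh1ko against Q140, the real one included (2 genes, highest other 514, which points to a structure of the samples). These splits also break up the sex difference common to the genotypes, so they cannot decide whether chance gave this count. With a real count of 0 all 50 splits give as many by construction for Q140 against WT (highest other 7) and Mlh1ko against WT (highest other 1), which says nothing about chance.

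For the gene lists, camera was run on signed z values of the gene tests, so the real counts differ somewhat from those of the report. Chance is not excluded for any of the 12 counts of lists. Splits of 100 with as many lists were 21 for Q140 against WT (14 lists, highest other 23), 62 for Q140_Mlh1het against Mlh1het (10, highest other 25), 24 for Q140_Mlh1ko against Mlh1ko (18, highest other 23), 47 and 52 for the interactions with 1 and no intact allele (11 and 12, highest other 26 and 22) and 35 for the averaged knock-in effect (16, highest other 25). They were 49 for Mlh1ko against WT (11, highest other 21), 67 for Q140_Mlh1ko against Q140 (10, highest other 22), 81 for the averaged Mlh1ko effect (8, highest other 24), 58 for Mlh1het against WT (12, highest other 23), 56 for Q140_Mlh1het against Q140 (10, highest other 20) and 37 for the averaged Mlh1het effect (13, highest other 23).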

How the results depend on the processing

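The alternatives with the GC trend removed, with libraries left out by principal component or choroid plexus transcripts, with each library left out of the list tests and with DESeq2's p adjusted over all genes were chosen after the data were seen. The cause of a changed value was not tested unless stated. With DESeq2, which changes the test and by its own filter the genes adjusted over, the counts were 27 for Q140 against WT, 1 for Mlh1het against WT, 4 for Mlh1ko against WT, 2 for Q140_Mlh1het against Q140, 15 for Q140_Mlh1ko against Q140, 1 for Q140_Mlh1ko against Mlh1ko, 19 for the averaged knock-in effect and 31 for the sex difference of Q140_Mlh1ko against Q140. Adjusted over all genes with a p, the first of these was 2 in place of 27. With no sex term Mlh1ko against WT gave 6. Genes within 10 Mb of Mlh1 and Htt were left out of the count only, and the adjustment over all tested genes was kept. The counts were then 0 for Mlh1ko against WT, Q140_Mlh1het against Q140, Q140_Mlh1ko against Q140 and the averaged Mlh1het effect. The averaged knock-in effect gave 2. Q140_Mlh1het against Q140 gave 0 with only the libraries compared, with a replicate block, with the well column, and without the choroid plexus libraries. The well column gave 4 for the averaged Mlh1ko effect, and no low-count filter gave 1 for the interaction with 1 disrupted allele.

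Without Q140 female replicates 1 and 3 the counts were 52 for Q140_Mlh1het against Q140, 207 for Q140_Mlh1ko against Q140, 7 for the averaged knock-in effect (also 7 with the GC trend removed as well) and 15 for the averaged Mlh1ko effect. The counts of lists were then 9 for Q140 against WT, 3 for Q140_Mlh1het against Q140, 4 for Q140_Mlh1ko against Q140 and 3 for the averaged Mlh1het effect. A replicate block gave 16 lists for Mlh1het against WT and 11 for the averaged Mlh1het effect. With an estimated correlation 0 lists passed in all 12 contrasts. Over all genes the direction r was 0.173 with Q140_Mlh1ko against Mlh1ko and -0.473 with Q140_Mlh1ko against Q140, where shared libraries alone gave a mean of -0.554 (covariance -0.014 against a simulated -0.0108), and with the Q140 libraries split between both comparisons the latter averaged 0.00849, and -0.0681 over the 200 genes with the smallest p.

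Leaving out 1 library at a time gave 0 to 2 genes for Q140 against WT (2 without Q140 male replicate 1), 0 to 1 for Mlh1het against WT (1 without WT male replicate 2), 2 to 7 for Mlh1ko against WT, 0 to 8 for Q140_Mlh1het against Q140, 2 to 15 for Q140_Mlh1ko against Q140, 0 to 3 for Q140_Mlh1het against Mlh1het, 0 to 0 for Q140_Mlh1ko against Mlh1ko and both interactions, 7 to 13 for the averaged knock-in effect, 8 to 11 for the averaged Mlh1ko effect and 2 to 2 for the averaged Mlh1het effect. For the lists it gave 9 to 17 for Q140 against WT, 4 to 14 for Mlh1het against WT, 5 to 13 for Mlh1ko against WT, 3 to 14 for Q140_Mlh1het against Q140, 8 to 12 for Q140_Mlh1ko against Q140, 5 to 16 for Q140_Mlh1het against Mlh1het, 9 to 18 for Q140_Mlh1ko against Mlh1ko, 6 to 17 and 10 to 15 for the interactions with 1 and no intact allele, 13 to 19 for the averaged knock-in effect, 6 to 13 for the averaged Mlh1ko effect and 0 to 13 for the averaged Mlh1het effect. Single values changed sign for the Tgm1 log2 fold change, Q140_Mlh1ko vs Mlh1ko, with a replicate block (-0.000797), the Mlh1 log2 fold change, Q140 by Mlh1ko interaction, with the well column (-0.077), and the Htt level: Q140_Mlh1ko against Mlh1het, in log2(FPKM + 0.1) (0.0053), all near 0. Among the genes named, DESeq2 put 5 more past the threshold, no sex term 2 more and no low-count filter 1 more, while 9 fell below it with the well column, 3 with limma-voom and the name number, and 2 or fewer with each of the other settings chosen before the data were examined. What depth limits was not tested by expression level.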

Other observations

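The test of male against female mice was chosen after the data were examined, and so were the genes named here. Between 24 males and 24 females, 141 of 19991 autosomal genes passed an adjusted p of 0.05, 70 higher in males and 71 in females, with 2943 at an unadjusted p under 0.05. Of 50 splits of the sexes, 1 gave as many, the real one, and the highest other gave 34, so chance is excluded for this count. Pcdhb3 was lower in males by a log2 difference of -0.31 (SE 0.0439, adjusted p = 9.78e-06, 0 of 24 males above the female mean), Wnt2 by -0.46 (SE 0.0807, adjusted p = 0.000711, 0 of 24) and Prdm16 higher by 0.18 (SE 0.0368, adjusted p = 0.0063, 23 of 24). On the X chromosome 13 of 747 genes passed and on the Y chromosome 6 of 8.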
